A study of Mus musculus with 12 samples.

How the data were processed

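Total RNA from the livers of male C57BL/6 mice was sequenced in 12 libraries, 1 per liver sample. The mice were 8 weeks old and wild type or knockout for TRIM21, apart from 1 mouse labelled heterozygous. Each had received a single intraperitoneal injection of 200 mg/kg diethylnitrosamine (DEN) in PBS, or of PBS, and liver was taken 48 h later. Per the labels' protocols, RNA was purified with RNeasy kits and about 500 ng went into a ribosomal RNA depletion library. Nothing was paired, because no number in the sample titles occurred in more than 1 group. The titles give each library its own number but do not state that each number is a separate animal, so p-values measure the spread between these samples.

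The authors deposited raw read counts per gene symbol, 1 column of counts per file, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq, TopHat2 and HTSeq and the genome build was mm9. Versions, the gene annotation, read trimming and the strand setting of the counting are not given in the sources used here. Without a strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical family members such as the Cyp2c, Gstm, Ugt2b, Mup, Saa and histone genes may share reads or lose them to the tally of reads with several alignments. Values for such genes are therefore uncertain.

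Each file held 22609 gene symbols and 5 tally lines that name no gene. The tally lines made up 61.4% to 78.7% of all counts listed, nearly all of them in the tally of alignments that were not unique. They were left out of library sizes and tests. Whether a read with several alignments adds 1 or more counts to this tally is not given. Per gene count there were 1.42 to 2.12 counts in this tally in the DEN libraries and 2.38 to 3.54 in the PBS libraries, which need not be shares of reads. Gene counts totalled 17303124 to 23059252 per library. Confidence intervals of single counts are exact at the 95% level. They and the floors used for counts of 0 cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries were compared by a chi-square of their counts over genes, which gave 24.8 to 83.7 per degree of freedom, so no pair came close to sampling noise.

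Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with the robust spread estimate, TMM scaling and the filterByExpr filter by group, which kept 13255 genes. One fit held the 11 libraries of 4 groups, namely 3 DEN wild-type, 2 DEN knockout, 3 PBS wild-type and 3 PBS knockout libraries, so that all groups shared 1 estimate of the spread. The library labelled heterozygote was left out of the fit because it was the single one of its kind, and its values are given beside the others. There were 5 comparisons: DEN against PBS in each genotype, knockout against wild type under each treatment, and the interaction, which is the DEN response of the knockout minus that of the wild type. P-values were adjusted by Benjamini and Hochberg within each comparison and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the root of its F statistic. CPM values use the TMM-scaled library sizes. The TMM factors were 1.12 to 1.28 in the DEN libraries and 0.839 to 0.895 in the PBS libraries. Small changes between DEN and PBS, such as that of Keap1, therefore depend on the scaling. Where a group had no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its exact counting interval.

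Before the data were examined, 31 gene lists were fixed, covering metabolic and stress pathways, immune genes, markers of liver cell types and of other tissues, and the neighbours of Trim21. Some genes belong to several lists, such as Cyp1a2 and Cyp2e1 to the pericentral and cytochrome P450 lists and Cyp4a14 to the cytochrome P450 and PPAR-alpha lists. Results of such lists are not independent. The 29 lists with at least 5 tested members were tested with camera on voom values in limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the lists within each comparison. Camera with the correlation estimated from the data and fry, which tests whether the genes of a list move one way on balance, were alternatives. Counts of list members are given over all tested genes and adjusted over the list alone. The neighbours of Trim21 were all annotated genes that start within 5 Mb of it in a later mouse assembly than the one the counts used. That annotation served for gene names and neighbourhood only, and 286 of its 448 genes there matched a symbol in the files.

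The genes named in the text followed a rule fixed before the data were examined. It takes Trim21 in every library, and for each comparison the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 1 on the log2 CPM scale and with no overlap between the libraries of both groups. The overlap condition was dropped for the interaction, and symbols of predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and unnamed clones were skipped. It adds up to 2 members higher and 2 lower with the smallest adjusted p for each list described, and always Nqo1, Gclc, Hmox1, Txnrd1, Sqstm1, Keap1, Nfe2l2, Mki67, Ccnb1, Ccnd1, Pcna, Cdkn1a, Mdm2, Cyp2e1, Il6, Tnf and Il1b. Where fewer than 5 genes were called, the 5 with the smallest p are named as such.

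The alternatives were DESeq2 1.42.0, limma-voom, relative log and upper-quartile scaling, no low-count filter, a stricter filter of 1 CPM in 3 libraries, only the groups of a comparison in the fit, the library labelled heterozygote counted with the wild type or as a group of its own, no robust spread estimate, an absolute log2 fold change of at least 1, and leaving out each library in turn. Where this left a group with 1 library, that library was assumed to vary like the other groups. Principal components were taken from the 500 most variable genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

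The test was tested on simulated data for each comparison, with 200 genes changed in counts drawn from the means and sizes of the real libraries. For DEN against PBS in wild type, edgeR recovered 13.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 90.9% of those changed 4-fold, among 12782 genes. The same shares were 9.0%, 49.3% and 80.3% for DEN against PBS in knockout among 12913 genes, and 10.4%, 65.7% and 87.9% for knockout against wild type under PBS among 12976 genes. For knockout against wild type under DEN they were 6.0%, 53.7% and 78.8%, and for the interaction 0.0%, 20.9% and 72.7%, each among 12913 genes. Between 1 and 9 unchanged genes were called per comparison and no recovered gene had the wrong sign. Only 200 genes were changed and each gene was drawn independently. In the real data 7402 of 13255 genes were called for DEN in wild type, and livers of 1 group also differed along changes shared by many genes. These shares and numbers of false calls therefore need not hold for the real comparisons. A slope of the knockout on the wild-type response was also tested on simulated data in which the knockout responded fully. It came out at 0.935 over genes chosen in the wild type and at 0.992 over genes chosen in the knockout. With a knockout response of 0.6 of the wild-type one, the same slopes were 0.565 and 0.643. Differences between livers of 1 genotype were compared with 20 simulated sets of libraries, drawn from the group means and the spread of each gene independently.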

Results

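The livers of TRIM21 wild-type and knockout male mice were profiled by ribosomal RNA-depleted RNA sequencing 48 h after a single dose of diethylnitrosamine (DEN) or of its PBS vehicle. TRIM21 is a cytosolic E3 ubiquitin ligase and antibody receptor. DEN is a hepatotoxic carcinogen that pericentral cytochrome P450 enzymes, chiefly CYP2E1, convert into a DNA-alkylating species. The title of the series speaks of antioxidant capacity and compensatory proliferation in the knockout livers, so genes of both processes were among the lists and genes fixed beforehand. There were 3 DEN wild-type, 2 DEN knockout, 3 PBS wild-type and 3 PBS knockout libraries, plus 1 DEN library labelled heterozygote. Libraries are named by their titles, such as DENKO_141. Gene counts totalled 18617881 to 23059252 in the DEN libraries and 17303124 to 22715563 in the PBS libraries.

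Trim21, the targeted gene, had at most 5 counts in every knockout library. It had 104, 127 and 93 counts in the PBS wild-type libraries PBSWT_541, PBSWT_542 and PBSWT_545 and 166, 113 and 225 counts in the DEN wild-type libraries DENWT_307, DENWT_995 and DENWT_996. The PBS knockout libraries PBSKO_154, PBSKO_544 and PBSKO_549 had 3, 5 and 5 counts and the DEN knockout libraries DENKO_141 and DENKO_309 had 3 each. This was 3.71% of the wild-type level under PBS (exact 95% counting interval 1.95% to 6.43%) and 1.82% under DEN (0.66% to 3.99%). In edgeR the log2 fold change was −4.71 ± 0.28 (SE, adjusted p = 3.3e-06, n = 3 and 3) under PBS and −5.68 ± 0.35 (adjusted p = 2.3e-06, n = 2 and 3) under DEN. The library labelled heterozygote had 7 Trim21 counts, 0.286 CPM, which was 4.26% of the DEN wild-type level (1.71% to 8.85%). That interval includes the knockout level, so the count goes against the label of this library.

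**Figure D1:**
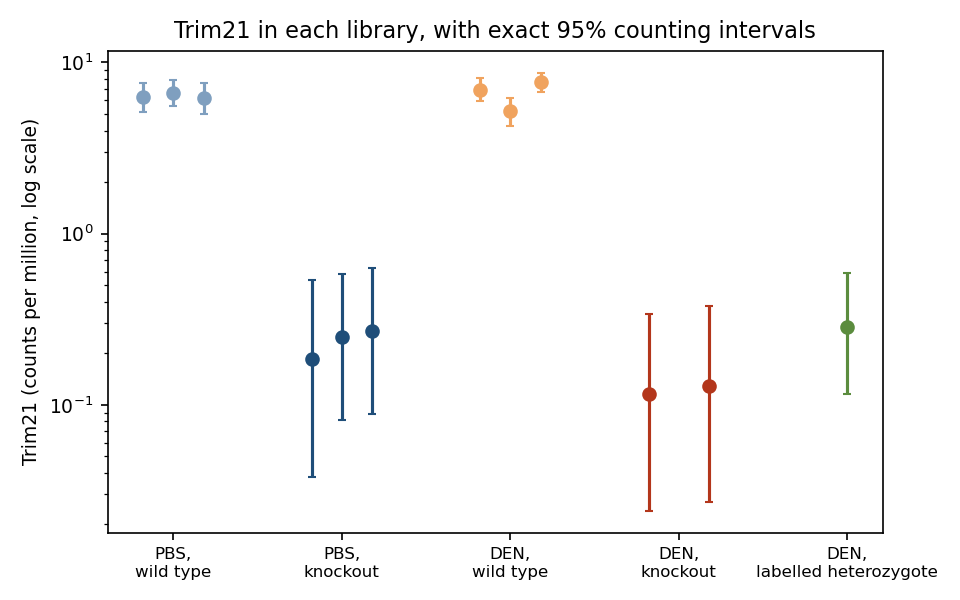
Trim21 in each of the 12 libraries, in CPM on a log axis, by treatment and genotype; points are libraries and bars their exact 95% counting intervals. Wild-type libraries lay between 5.17 and 7.65 CPM, knockout libraries between 0.116 and 0.271 CPM, and the library labelled heterozygote at 0.286 CPM.

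DEN treatment set the libraries apart more than genotype did. The first principal component held 85.5% of the variance and placed the 6 PBS libraries between −43.4 and −38.8. The DEN wild-type libraries lay between 47.3 and 54.1 on it, the DEN knockout libraries DENKO_141 and DENKO_309 at 18.3 and 28.7, and the library labelled heterozygote at 54.8. Across tested genes, this library correlated at 0.961 to 0.972 with the DEN wild-type libraries and at 0.909 to 0.926 with the DEN knockout libraries, as a description across genes, which are not independent replicates.

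**Figure D2:**
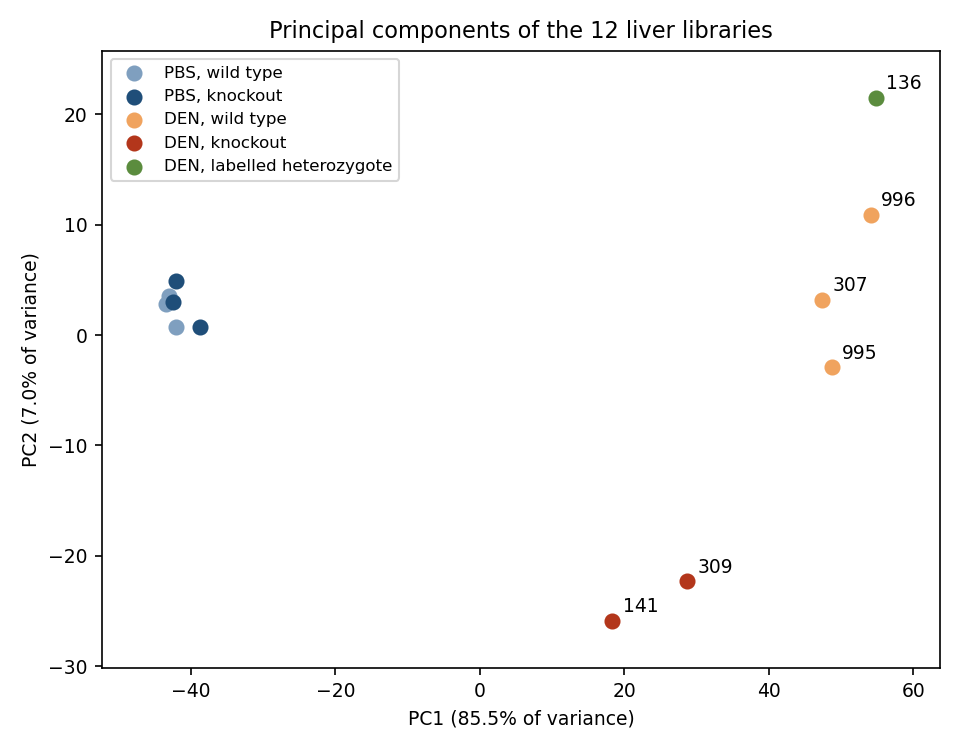
The 12 libraries on the first and second principal component of the 500 most variable genes, with the share of variance on each axis; each point is 1 library, coloured by group, and the DEN libraries carry their numbers. The DEN knockout libraries DENKO_141 and DENKO_309 lie at 18.3 and 28.7 on the first component, between the PBS libraries and the DEN wild-type libraries.

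The first comparison asked what DEN did to wild-type liver. After DEN, 33 of 40 tested targets of the tumour suppressor p53 were higher and 23 of 25 genes of pericentral hepatocytes, the cells around the central vein in which DEN is activated, were lower. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 7.34 ± 6.42 CPM under PBS to 1098 ± 161 CPM under DEN (SD, n = 3 each). Cyp1a2, a pericentral cytochrome P450, fell from 1685 ± 94.9 to 10.4 ± 2.40 CPM. Of 13255 tested genes, 7402 changed in edgeR, 3868 higher and 3534 lower, and of these 1775 rose and 1801 fell by at least 2-fold.

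Of 40 tested p53 targets and DNA damage genes, 33 rose, 1 fell and 6 did not pass, with the same numbers adjusted over the list alone and a median log2 fold change of 2.72. Phlda3, a p53-induced repressor of AKT signalling, rose by 6.72 ± 0.22 log2 units (adjusted p = 1.2e-09) and Eda2r, a death receptor of the TNF receptor family, by 7.40 ± 0.28 (2e-09). Mdm2, the ubiquitin ligase of p53, rose by 3.06 ± 0.12 (2.3e-09) and Cdkn1a by 7.24 ± 0.62 (1.2e-05). Sesn1, a stress-induced regulator of mTORC1, was the single member that fell, at −0.61 ± 0.15 (0.0033). The list was higher in camera (adjusted p = 5.4e-14, and adjusted p = 0.13 with an estimated correlation). Immediate early genes, transcription factors and regulators switched on within minutes of a stimulus, rose in 17 of 24 (18 adjusted over the list alone) and none fell, with a camera adjusted p of 4.7e-07 and an adjusted p = 0.29 with an estimated correlation. Among them Klf6 rose by 3.91 ± 0.24 (1.9e-07), and Egr2, without a count in the PBS wild-type libraries, was at least 109-fold higher.

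Of 25 pericentral genes, 23 fell, none rose and 2 did not pass (24 lower adjusted over the list alone), with a median log2 fold change of −3.95. The glutamate transporter gene Slc1a2 fell from 333 ± 28.1 to 1.21 ± 0.469 CPM, a log2 fold change of −8.09 ± 0.30 (adjusted p = 2e-09). Rgn, which encodes a gluconolactonase of ascorbate synthesis, fell by 5.72 ± 0.25 (5.8e-09). Cyp2e1 fell by 3.86 ± 0.59 (0.00034). The camera adjusted p was 1.4e-13 (adjusted p = 0.25 with an estimated correlation). Male-biased liver genes fell in 24 of 28 and rose in none, the same adjusted over the list alone, with a median of −2.48 and a camera adjusted p of 1.1e-11 (adjusted p = 0.18 with an estimated correlation). Nudt7, a peroxisomal coenzyme A hydrolase, fell by 4.17 ± 0.26 (8.1e-08), and Hsd3b5, a steroid dehydrogenase of male liver, fell by 8.43 ± 0.60 (3.5e-06).

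Metabolic lists were lower as well. Of 42 cytochrome P450 genes 29 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 1.4e-06, and adjusted p = 0.38 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase, was among those that rose, by 7.03 ± 0.87 (0.00017), and Cyp2c44 fell by 3.14 ± 0.25 (8.2e-07). Of 23 cholesterol synthesis genes 18 fell (20 adjusted over the list alone) and none rose, among them the sterol reductase gene Tm7sf2 at −3.24 ± 0.18 (3.8e-08), with a camera adjusted p of 2.2e-07 and an adjusted p = 0.38 with an estimated correlation. Of 21 fatty acid synthesis genes 16 fell and 2 rose, the same adjusted over the list alone, among the former Mlxipl, the carbohydrate-responsive transcription factor ChREBP, at −2.59 ± 0.18 (2.3e-07). The camera adjusted p of this list was 1.5e-05 (adjusted p = 0.38 with an estimated correlation). Targets of PPAR-alpha, the receptor that drives fatty acid oxidation, went the other way, with 18 of 30 higher (20 adjusted over the list alone) and 5 lower, at a camera adjusted p of 0.0011 (adjusted p = 0.53 with an estimated correlation). Ehhadh of peroxisomal beta-oxidation rose by 1.80 ± 0.16 (1.6e-06) and Acot1, an acyl-CoA thioesterase, by 3.04 ± 0.26 (2.8e-06).

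NRF2 targets, the antioxidant and detoxification genes under this transcription factor, went both ways in wild-type liver, with 14 of 40 higher and 17 lower (14 and 18 adjusted over the list alone, camera adjusted p = 0.33). Srxn1, which repairs peroxiredoxins, rose by 2.53 ± 0.14 (3.9e-08), Hmox1, heme oxygenase 1, by 1.72 ± 0.21 (2e-05), Gclc, the catalytic subunit of glutathione synthesis, by 1.22 ± 0.20 (0.00018), Txnrd1, thioredoxin reductase 1, by 0.70 ± 0.12 (0.00033) and the quinone reductase gene Nqo1 by 0.65 ± 0.23 (0.031). The glutathione transferase genes Gstm6 and Gsta4 fell by 2.76 ± 0.22 (8.8e-07) and 3.44 ± 0.35 (2.1e-05). Keap1, the inhibitor of NRF2, fell by 0.36 ± 0.12 (0.023), while Nfe2l2, which encodes NRF2, and Sqstm1, which encodes p62, had values of 0.31 ± 0.15 and 0.26 ± 0.15 and did not pass. The calls of Nqo1 and Keap1 were each lost in 3 of the 11 fits that left out a library, with adjusted p up to 0.11 and 0.086.

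Interferon-stimulated genes were lower in DEN wild-type liver, with 26 of 41 lower and 3 higher (27 and 3 adjusted over the list alone, median −1.08, camera adjusted p = 1.5e-05, and adjusted p = 0.56 with an estimated correlation). The immunoproteasome subunit gene Psmb8 fell by 1.90 ± 0.13 (2.4e-07) and Bst2, the antiviral tetherin, by 1.93 ± 0.16 (9.4e-07), whereas Tap1, a peptide transporter, rose by 1.37 ± 0.14 (5.9e-06). Markers of T, NK and B lymphocytes were lower in 10 of 19 and higher in none, the same adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.38 with an estimated correlation), with Cd4 at −3.94 ± 0.52 (4.4e-05). Markers of monocytes and neutrophils were higher in 13 of 19 and lower in 1, the same adjusted over the list alone (camera adjusted p = 0.02, 0.051 without PBSWT_541, and adjusted p = 0.64 with an estimated correlation), with Ltf, the neutrophil granule protein lactoferrin, at 8.86 ± 0.97 (7.9e-05). Of 50 cell cycle genes 14 rose and 17 fell, the same adjusted over the list alone (camera adjusted p = 0.33). The replication helicase gene Mcm7 rose by 2.59 ± 0.30 (2.8e-05) and Pcna, the replication clamp, by 0.67 ± 0.14 (0.0011), while Mki67, the Ki-67 marker of cycling cells, fell by 2.31 ± 0.47 (0.001) and Ccnd1, cyclin D1, by 2.08 ± 0.46 (0.0038). The cytokine genes Tnf and Il1b had values of 0.19 ± 0.85 and −0.04 ± 0.54 and did not pass, and Ccnb1 and Il6 had too few counts to be tested.

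The largest rises in wild type included Ivl, a precursor of the cornified envelope, and Rprm, a p53-induced cell cycle inhibitor, without a count under PBS and at least 239-fold and 98.5-fold higher under DEN. Fosl1, an AP-1 subunit with 3 counts over the PBS libraries, was 384-fold higher (exact 95% counting interval 131 to 1.86e+03). Among the largest falls were Serpina6, which encodes corticosteroid-binding globulin, at −6.97 ± 0.58 (1.1e-05), and Syt1, a synaptotagmin, at −7.40 ± 0.36 (1.2e-08). No DEN wild-type library overlapped the PBS wild-type libraries for the genes named here as risen or fallen, which the rule for named genes required of the largest changes and which is therefore no test of its own. Without each library in turn 6220 to 7687 genes were called.

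The same treatment was then compared in knockout liver. Here 30 of 40 p53 targets rose and 14 of 25 pericentral genes fell. Of 13255 tested genes 3010 changed, 1594 higher and 1416 lower, with 2 DEN libraries against 3 PBS libraries. Without DENKO_309, 1161 genes were called. Cdkn1a rose from 8.92 ± 3.35 CPM (SD, n = 3) to 714 ± 29.3 CPM (SD, n = 2), a log2 fold change of 6.32 ± 0.61 (adjusted p = 0.00012). Slc1a2 fell from 338 ± 87.3 to 1.38 ± 0.0106 CPM.

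Of 40 p53 targets 30 rose and none fell (32 and 0 adjusted over the list alone), with a median of 1.78. Phlda3 rose by 6.47 ± 0.23 (2.5e-09), Ccng1, a p53-induced cyclin, by 3.91 ± 0.16 (8e-09) and Mdm2 by 2.84 ± 0.13 (1.3e-08). This was the only list called both with the preset correlation (camera adjusted p = 1.2e-23) and with an estimated one (adjusted p = 0.029 with an estimated correlation). Of 25 pericentral genes 14 fell and none rose, with 16 lower and 1 higher adjusted over the list alone (median −1.41, camera adjusted p = 1.5e-08, and adjusted p = 0.32 with an estimated correlation). Slc1a2 fell by 7.92 ± 0.36 (1.4e-08) and Glul, glutamine synthetase, by 4.86 ± 0.28 (9.2e-08). Cyp2e1 fell by 2.59 ± 0.65 (0.018), a call that was lost without DENKO_141 (adjusted p = 0.11) and without DENKO_309 (adjusted p = 0.13). Male-biased genes fell in 20 of 28, the same adjusted over the list alone, and rose in none (camera adjusted p = 7.1e-14, and adjusted p = 0.12 with an estimated correlation), among them Nudt7 at −3.53 ± 0.30 (3.3e-06).

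NRF2 targets in knockout liver were higher in 16 of 40 and lower in 3 (16 and 6 adjusted over the list alone), with a negative median of −0.15 but a positive mean of 0.37 and a camera direction of higher that did not pass (adjusted p = 0.19), but did without DENKO_309 (0.012) or PBSKO_549 (0.049). Srxn1 rose by 2.01 ± 0.15 (1.1e-06), Hmox1 by 1.85 ± 0.22 (9.6e-05) and Txnrd1 by 0.66 ± 0.13 (0.0038). Nqo1 rose from 9.19 ± 3.16 to 25.8 ± 6.60 CPM (0.0012). Nfe2l2 rose by 1.13 ± 0.16 (0.00038). The cystine transporter gene Slc7a11, with 1 count over the PBS knockout libraries, was 194-fold higher (exact 95% counting interval 34.3 to 7.7e+03). Gclc rose by 0.97 ± 0.21 (0.006), which did not pass without DENKO_141 (0.063), and Sqstm1 had a value of 0.23 ± 0.17 and did not pass. Keap1 fell by 0.41 ± 0.14 (0.048), a call lost in 10 of 11 fits that left out a library, with adjusted p up to 0.45. Interferon-stimulated genes were higher in 5 and lower in 2 of 41 (4 and 2 adjusted over the list alone, camera adjusted p = 0.23), and the list was called higher without DENKO_309 (0.0058) or PBSKO_549 (0.003). Cell cycle genes were lower in 3 of 50 and higher in none, with none called adjusted over the list alone (camera adjusted p = 0.86), with Mki67 at −0.02 ± 0.45 and Ccnd1 at 0.21 ± 0.47, neither of which passed, nor did Pcna at 0.42 ± 0.15. Tnf rose by 2.26 ± 0.74 (0.042), a call lost in 6 of 11 fits, and Il1b had a value of −0.94 ± 0.58 and did not pass. Markers of monocytes and neutrophils were higher in 12 of 19 and lower in none (14 and 1 adjusted over the list alone, camera adjusted p = 9.6e-07, and adjusted p = 0.32 with an estimated correlation), with Ltf at 7.88 ± 0.87 (0.00038).

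The largest rises in knockout included Zfp365, a p53-induced gene of genome stability, 478-fold higher (163 to 2.32e+03) and Lif, a cytokine of the IL-6 family, 179-fold higher (60.9 to 871), each with 3 counts over the PBS knockout libraries. Among the falls were Fhit, a diadenosine triphosphatase, at −6.34 ± 0.42 (4.7e-07) and Slc22a3, an organic cation transporter, at −5.57 ± 0.57 (2.6e-05). Of the 110 named genes called in this comparison, 75 kept the call whichever library was left out, and 32 lost it without DENKO_309.

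**Figure D3:**
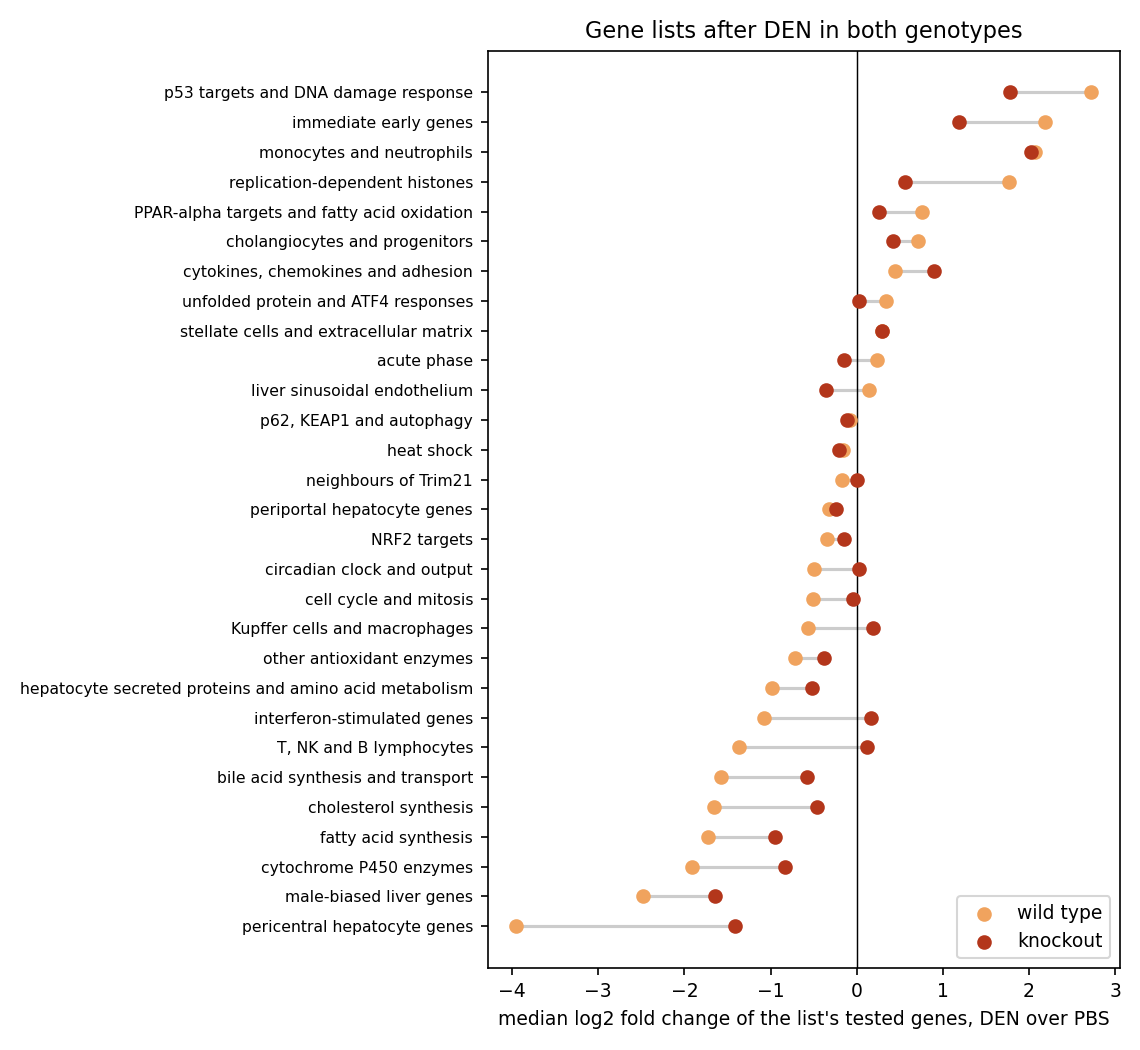
Median log2 fold change, DEN over PBS, of the tested genes of 29 gene lists, in wild type and in knockout; each line joins both values of 1 list. Pericentral hepatocyte genes had medians of −3.95 in wild type and −1.41 in knockout, p53 targets of 2.72 and 1.78, and interferon-stimulated genes of −1.08 and 0.17.

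Knockout and wild-type livers were next compared under PBS, to see what the loss of TRIM21 did without injury. Trim21 itself was the only gene called in edgeR, at −4.71 ± 0.28 (adjusted p = 3.3e-06). At an unadjusted p under 0.05, 508 genes passed, 3.8% of those tested, and DESeq2 and limma-voom each called 1 gene. The next genes by p did not pass and had an adjusted p of 1, namely Fnip2, a folliculin-interacting protein, at −0.74 ± 0.15, Mid1, another TRIM family ligase, at 0.84 ± 0.18, Creld2, an endoplasmic reticulum stress gene, at 0.71 ± 0.16 and Atp11a, a lipid flippase, at 1.01 ± 0.23. Nqo1 had a value of −0.14 ± 0.24, Gclc of 0.28 ± 0.19, Sqstm1 of −0.01 ± 0.15, Cyp2e1 of 0.12 ± 0.52 and Mki67 of −0.09 ± 0.41, none of which passed. On simulated data this comparison recovered 65.7% of genes changed 2-fold and 10.4% of those changed 1.5-fold.

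No list had a member called over all genes tested. Adjusted over the list alone, 1 of 28 unfolded protein and ATF4 response genes, Creld2, and 1 of 4 adipose and pancreas genes, Fabp4, a fatty acid binding protein, were higher in knockout. Fabp4 had a value of 0.93 ± 0.30 and is named after its values were seen. Camera called 11 of 29 lists with the preset correlation, none with an estimated one (lowest adjusted p = 0.63 with an estimated correlation), and fry called none. The smallest camera value belonged to markers of liver sinusoidal endothelium (median 0.25, adjusted p = 9.3e-07, and adjusted p = 0.63 with an estimated correlation), and this call was lost without PBSWT_541 (0.83). The mean of these markers, as a log2 difference from all PBS libraries, was −0.76 in PBSWT_541, 0.15 and 0.13 in the other PBS wild-type libraries, and 0.19, 0.39 and −0.10 in the PBS knockout libraries. Among the lists that camera called, only acute phase genes kept the call whichever library was left out. They were higher in knockout (median 0.23, camera adjusted p = 0.0013, and adjusted p = 0.63 with an estimated correlation). NRF2 targets had a median of −0.01 (camera adjusted p = 0.87), p53 targets of 0.00 (0.87) and cell cycle genes of −0.02 (0.98). Genes within 5 Mb of Trim21, which can carry variants of the strain the knockout was made in, had a median of 0.01 (0.98), and 5 of 83 (6.0%) passed an unadjusted p under 0.05, against 3.8% of other genes.

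After DEN the libraries labelled knockout and wild type did differ, with 2 knockout livers. The library labelled heterozygote, whose Trim21 count was near the knockout level, was nearer to the knockout mean in 7.3% of the called genes. No fit counted it as knockout. In knockout livers 17 of 25 pericentral hepatocyte genes, 29 of 41 interferon-stimulated genes and 8 of 19 lymphocyte markers were higher than in wild-type livers, and 7 of 24 immediate early genes and 8 of 30 PPAR-alpha targets were lower. Camera called these 5 lists with the preset correlation but none of them with an estimated one (adjusted p = 0.47 with an estimated correlation for each). Rgn was at 577 ± 235 CPM in knockout (SD, n = 2) and at 35.1 ± 4.13 CPM in wild type (SD, n = 3), a log2 fold change of 4.05 ± 0.24 (adjusted p = 2.3e-06), and Psmb8 at 30.9 ± 4.37 against 14.3 ± 1.68 CPM, a log2 fold change of 1.12 ± 0.14 (0.00071). Of 13255 genes 2927 were called, 1621 higher and 1306 lower in knockout. The number rested on few libraries, with 256 genes called without DENKO_141, 250 of them among the 2927, 1742 without DENKO_309 and 1300 without DENWT_996. Of the 99 named genes called in this comparison, 38 kept the call in all 11 fits that left out a library and 60 lost it without DENKO_141.

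Of 25 pericentral genes 17 were higher in knockout and none lower (22 and 0 adjusted over the list alone, median 1.38, camera adjusted p = 1.8e-12, and adjusted p = 0.47 with an estimated correlation). Besides Rgn, Gulo, the gulonolactone oxidase of vitamin C synthesis, was higher by 2.44 ± 0.19 (2.8e-05) and Cyp1a2 by 5.73 ± 0.47 (0.00019), and all 3 kept their calls without each library in turn. Cyp2e1 had a value of 1.38 ± 0.58 and did not pass (0.11). Of 42 cytochrome P450 genes 16 were higher and 3 lower (18 and 3 adjusted over the list alone, camera adjusted p = 5.1e-05, and adjusted p = 0.47 with an estimated correlation). Cholesterol synthesis genes were higher in 11 of 23 and lower in none (15 and 0 adjusted over the list alone, camera adjusted p = 7.1e-07, and adjusted p = 0.47 with an estimated correlation), among them Tm7sf2 at 1.53 ± 0.19 (0.00059). Mlxipl of fatty acid synthesis was higher by 1.91 ± 0.19 (0.00019), in a list with 6 of 21 higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.055), which camera called without DENKO_309 (0.00079), DENWT_996 (0.029), PBSKO_154 (0.046) or PBSKO_549 (0.045). PPAR-alpha targets were lower in 8 of 30 and higher in none (12 lower adjusted over the list alone, camera adjusted p = 3.6e-06, and adjusted p = 0.47 with an estimated correlation), among them the lipid droplet gene Cidec, at 21.3 ± 14.4 against 155 ± 32.1 CPM, a log2 fold change of −2.87 ± 0.42 (0.0032).

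Of 41 interferon-stimulated genes 29 were higher in knockout and none lower (36 and 0 adjusted over the list alone, median 1.04, camera adjusted p = 5.3e-14, and adjusted p = 0.47 with an estimated correlation). Psmb8 and Bst2, at 1.24 ± 0.17 (0.0011), kept their calls without each library in turn. A list of 13 pan-leukocyte genes, added after the data were examined, had a median of 1.16 in the same comparison. Markers of lymphocytes were higher in 8 of 19 and lower in none (11 and 0 adjusted over the list alone, median 1.49, camera adjusted p = 4.7e-05, and adjusted p = 0.47 with an estimated correlation). The cytotoxic granule gene Nkg7 was higher by 2.89 ± 0.54 (0.0043, and 0.07 without DENKO_141) and the T cell coreceptor gene Cd8a by 2.70 ± 0.57 (0.007, and 0.12 without DENKO_141), with at most 0.849 and 1.16 CPM in any DEN library. Markers of Kupffer cells and macrophages were higher in 9 of 26 and lower in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.48 with an estimated correlation), with Mpeg1, the pore-forming perforin-2 of macrophages, at 1.34 ± 0.18 (0.0011) and Cd14, a lipopolysaccharide coreceptor, at −1.95 ± 0.26 (0.00078). Markers of monocytes and neutrophils were higher in 6 of 19 and lower in none (7 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 0.0097, and adjusted p = 0.56 with an estimated correlation), a camera call lost without DENKO_309 (0.075) or DENWT_996 (0.12). None of 24 endothelial markers was called (median −0.06, camera adjusted p = 0.89, with no call over the list alone). The cytokine Il18 was higher by 1.63 ± 0.21 (0.00066) and Tnf by 2.11 ± 0.69 (0.043), the latter from 20 and 24 counts against 7, 7 and 1 and with its call lost in 5 of 11 fits. Il1b had a value of −0.01 ± 0.59 and did not pass.

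Antioxidant genes were taken up because the series title names them. Of 40 NRF2 targets 13 were higher in DEN knockout liver and none lower (17 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 5.7e-05, and adjusted p = 0.47 with an estimated correlation). Aox1, aldehyde oxidase, was higher by 1.40 ± 0.20 (0.0014) and kept its call without each library in turn. Gclm, the modifier subunit of glutathione synthesis, was higher by 0.91 ± 0.16 (0.0034, and 0.064 without DENKO_141). Nfe2l2 was higher by 0.50 ± 0.17 (0.044), a call lost in 9 of 11 fits that left out a library. Nqo1 had a value of 0.71 ± 0.25 and did not pass (0.057), nor did Gclc at 0.02 ± 0.22 (0.95), Hmox1 at 0.08 ± 0.22 (0.83), Txnrd1 at 0.01 ± 0.14 (0.97), Sqstm1 at −0.05 ± 0.17 (0.87) and Keap1 at 0.01 ± 0.14 (0.95). Other antioxidant enzymes were lower in 17 of 28 and higher in 4 under DEN in wild type (18 and 4 adjusted over the list alone, camera adjusted p = 0.0005, and adjusted p = 0.38 with an estimated correlation). In knockout they were lower in 14 and higher in 4 under DEN, the same adjusted over the list alone (camera adjusted p = 0.0042, and adjusted p = 0.6 with an estimated correlation). Between the DEN genotypes they were higher in knockout in 8 of 28 and lower in 1 (11 and 2 adjusted over the list alone, camera adjusted p = 0.038, and adjusted p = 0.61 with an estimated correlation), among them Prdx6, a peroxiredoxin, at 0.84 ± 0.20 (0.012, and 0.14 without DENKO_141). This camera call was lost without DENKO_309 (0.16), DENWT_996 (0.12), PBSWT_541 (0.054), PBSWT_542 (0.052) or PBSWT_545 (0.052). The interaction called none of the 28, also over the list alone (camera adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation).

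Proliferation genes, the other subject of the title, went both ways. Against PBS, Mki67 and Ccnd1 fell under DEN in wild type and were not called in knockout, where 0 of 50 cell cycle genes were called higher. Mki67 was at 3.01 and 1.63 CPM in DENKO_141 and DENKO_309 and at 1.59 to 3.25 CPM in the PBS knockout libraries. Ccnd1 was at 35.8 CPM in DENKO_141 and 13.6 CPM in DENKO_309, and at 13.5 to 25.6 CPM in the PBS knockout libraries. For these 2 genes, higher values in DEN knockout than in DEN wild type thus came without a called rise above PBS. With 2 DEN knockout livers, which differed for Ccnd1, a missing call does not exclude a rise. Of 50 cell cycle genes 10 were higher in DEN knockout liver and 4 lower (11 and 5 adjusted over the list alone, median 0.43, camera adjusted p = 0.26). The list was called higher without DENKO_309 (0.0074). Mki67 was at 2.32 ± 0.975 CPM in knockout and 0.522 ± 0.292 in wild type, higher by 2.20 ± 0.50 (0.0093, and 0.14 without DENKO_141), and Ccnd1 was higher by 2.06 ± 0.49 (0.018, and 0.19 without DENKO_141), a call also lost without DENWT_996. The mitotic kinase gene Aurkb was higher by 2.51 ± 0.47 (0.0045, and 0.075 without DENKO_141), the thymidine kinase gene Tk1 by 2.34 ± 0.42 (0.0059, and 0.076 without DENKO_141). Lower were Mcm7 at −1.62 ± 0.32 (0.007, and 0.082 without DENKO_141) and Pcna at −0.53 ± 0.15 (0.026, and 0.17 without DENKO_141), a call lost in 3 of 11 fits. The p53 targets were higher in 2 and lower in 10 of 40 (2 and 14 adjusted over the list alone, median −0.37, camera adjusted p = 0.00018, and adjusted p = 0.47 with an estimated correlation), with the death receptor gene Tnfrsf10b at −1.07 ± 0.22 (0.0062, and 0.097 without DENKO_141). Cdkn1a and Mdm2 had values of −0.62 ± 0.53 (0.44) and −0.26 ± 0.13 (0.15) and did not pass. Immediate early genes were lower in 7 of 24 and higher in none (12 lower adjusted over the list alone, median −1.05, camera adjusted p = 7.1e-07, and adjusted p = 0.47 with an estimated correlation), with the stress-induced transcription factor gene Klf6 at −1.28 ± 0.25 (0.0053, and 0.083 without DENKO_141).

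Other large differences between the DEN genotypes were those of Hsd3b5, at 33.9 ± 0.547 against 0.816 ± 0.321 CPM and a log2 fold change of 5.39 ± 0.57 (0.0009), Slco1a1, an organic anion transporter, 24.3-fold (0.0017) and Serpina6 at 4.35 ± 0.55 (0.002). Lower in knockout were Igdcc4, an immunoglobulin family receptor, at −5.00 ± 0.57 (0.00037), Bmper, a regulator of BMP signalling, at −3.19 ± 0.40 (0.00066) and the acute phase gene Saa1 at −3.14 ± 0.93 (0.045, and 0.25 without DENKO_141), a call lost in 7 of 11 fits. Of the acute phase list 3 of 28 were higher and 6 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.31), and the list was called lower without DENKO_309 (0.03).

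**Figure D4:**
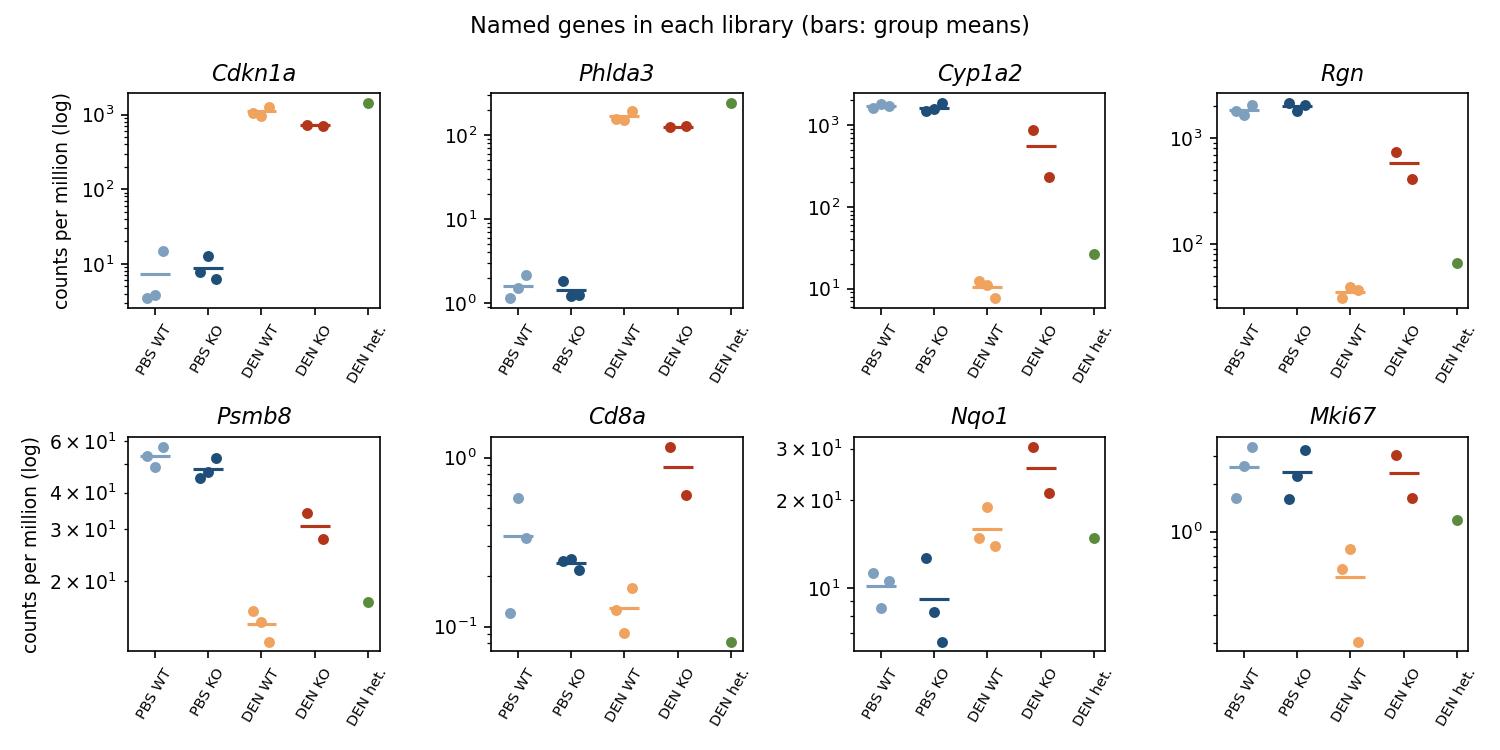
Cdkn1a, Phlda3, Cyp1a2, Rgn, Psmb8, Cd8a, Nqo1 and Mki67 in each library, in CPM on log axes; points are libraries and short bars group means. Rgn lay at 577 CPM on average in DEN knockout libraries and at 35.1 CPM in DEN wild-type libraries, while Cdkn1a averaged 714 and 1098 CPM in the same groups.

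The interaction asked whether DEN changed a gene by a different amount in the knockout. Differences are the log2 change under DEN in knockout minus that in wild type, so a positive difference can be a weaker fall. The difference was positive for 14 of 25 pericentral, 12 of 42 cytochrome P450 and 11 of 41 interferon-stimulated genes, of which 13, 12 and 6 had negative changes in both genotypes, smaller in size in knockout, and the others a negative change in wild type and a positive one in knockout. It was negative for 5 of 30 PPAR-alpha targets, of which 4 had positive changes in both genotypes, smaller in knockout. Camera called these 4 lists with the preset correlation but none of them with an estimated one (adjusted p = 0.39 with an estimated correlation for each). The pericentral and cytochrome P450 lists share members such as Cyp1a2, so their counts are not separate results. Fry called the pericentral list (0.021) and not the interferon-stimulated (0.073), cytochrome P450 (0.073) and PPAR-alpha (0.086) lists. Of 13255 genes 872 were called, 540 with a positive and 332 with a negative difference, and 26 without DENKO_141. Of the 540, 395 had negative changes in both genotypes that were smaller in size in knockout, and of the 332, 229 had positive changes in both that were smaller in knockout. There were 321 without DENWT_996, 372 without PBSKO_154, and 385, 222 and 257 without PBSWT_541, PBSWT_542 and PBSWT_545. DESeq2 called 1414 genes. Cyp1a2 changed by −7.35 log2 units in wild type and by −1.57 in knockout, a difference of 5.78 ± 0.58 (adjusted p = 0.0018), and Rgn by −5.72 and −1.79, a difference of 3.92 ± 0.31 (6.2e-05). Gulo, Serpina6 and Mlxipl also fell less in knockout, with differences of 2.54 ± 0.26 (0.00077), 4.33 ± 0.69 (0.016) and 1.93 ± 0.26 (0.0039). Tnfrsf12a, the TWEAK receptor, rose less in knockout, by 2.78 against 4.57, a difference of −1.79 ± 0.29 (0.0097). These and Fam55b, Slc22a28, Syt1 and Akr1c6 were the 10 of 63 named genes whose call survived each library left out.

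Of 25 pericentral genes 14 had a positive difference and none a negative one (16 and 0 adjusted over the list alone, median 1.41, camera adjusted p = 3.1e-13, and adjusted p = 0.39 with an estimated correlation). Cytochrome P450 genes had 12 of 42 positive and none negative (16 and 0 adjusted over the list alone, camera adjusted p = 8.1e-06, and adjusted p = 0.39 with an estimated correlation). PPAR-alpha targets had 5 of 30 negative and none positive, the same adjusted over the list alone (camera adjusted p = 8.1e-06, and adjusted p = 0.39 with an estimated correlation). For interferon-stimulated genes the counts were 11 of 41 positive and 0 negative (23 and 0 adjusted over the list alone, median 1.20, camera adjusted p = 2.5e-13, and adjusted p = 0.39 with an estimated correlation), with Psmb8 at 1.26 ± 0.19 (0.008, and 0.06 without DENKO_141) and Irf7, a transcription factor of the interferon response, at 1.71 ± 0.28 (0.01, and 0.081 without DENKO_141). NRF2 targets had 7 of 40 positive and none negative (11 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 0.00034, and adjusted p = 0.47 with an estimated correlation), with Aox1 at 1.21 ± 0.27 (0.027, and 0.17 without DENKO_141), a call lost in 5 of 11 fits. Of these 7 NRF2 targets, 4 had negative changes in both genotypes, smaller in size in knockout, 2 a negative change in wild type and a positive one in knockout, and 1 positive changes, larger in knockout. Nfe2l2 had a difference of 0.82 ± 0.22 (0.045), a call lost in 10 of 11 fits. Mki67 and Ccnd1 had differences of 2.29 ± 0.65 (0.052) and 2.29 ± 0.65 (0.068), and Nqo1 of 0.85 ± 0.35 (0.15), and did not pass. For cell cycle genes 3 of 50 were positive and 1 negative (4 and 1 adjusted over the list alone, camera adjusted p = 0.26), and the list was called positive without DENKO_309 (0.015). Of these 3, 2 had negative changes in both genotypes, smaller in size in knockout, and 1 a negative change in wild type and a positive one in knockout. The p53 targets had 1 of 40 negative and none positive, with none called adjusted over the list alone (median −0.32, camera adjusted p = 0.0054, and adjusted p = 0.41 with an estimated correlation).

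Across the 7402 genes called in wild type, the knockout log2 changes had a slope of 0.599 on the wild-type changes. It lay between 0.534 and 0.649 without each library in turn, and its jackknife SE from these fits was 0.099. Over the 3010 genes called in knockout the slope was 0.780 (0.752 to 0.859, jackknife SE 0.098). Such ranges, also those of the lists below, are not confidence intervals. Simulated libraries with a full response in knockout gave 0.935 and 0.992 for these choices of genes. With a knockout response of 0.6 of the wild-type one in every gene they gave 0.565 and 0.643. The observed 0.599 lay near the former of these and the observed 0.780 above the latter. The slope was 0.88 over p53 targets (0.85 to 0.91), 0.53 over pericentral genes (0.49 to 0.61), 0.66 over NRF2 targets (0.57 to 0.80), 0.14 over interferon-stimulated genes (−0.04 to 0.29) and 0.89 over macrophage markers (0.79 to 0.96). Both responses share no library. Among the genes called in each, 1318 rose in both and 1296 fell in both, against 465 and 378 for independent lists, and 13 went opposite ways.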

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

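The tests of Trim21 in the library labelled heterozygote, of the correlations between livers, of the slopes and of the hepatocyte share were chosen after their results had been seen, and those of the leukocytes and of the interferon-stimulated genes within the knockout before, with the pan-leukocyte list itself added after the data were examined.

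Trim21 in the DEN library labelled heterozygote was at 4.26% of the DEN wild-type level, in an interval that includes the 1.82% of the DEN knockout libraries, which is what a wrong label would give. The upper end of 8.85% argues against a working copy read at an intermediate level, and its depth of 20.7 M gene counts, above the 17.3 M of the lowest other library, argues against low depth. In 54.4% of the 2927 genes called between the DEN genotypes this library lay beyond every DEN wild-type library, on the side away from the knockout, and it was nearer to the knockout mean in 7.3%. If its Trim21 count rather than its label is right, a liver without Trim21 may thus have responded to DEN at least as far as the wild type. The label was kept, and which is right stays open.

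The difference between knockout and wild-type livers after DEN may partly be one in the degree of liver injury, which need not come from the genotype. Over all 13255 tested genes, DENWT_996 minus another DEN wild-type library correlated with knockout minus the third at r = −0.48 at the weakest, and at −0.63 over the 1300 genes called without DENWT_996, against −0.02 to −0.00 and −0.09 to −0.00 for the most negative wild-type library of each of 20 simulated sets where livers of a group differed by independent noise. DENKO_141 minus DENKO_309 against knockout minus wild type gave r = 0.31 over all tested genes (simulated −0.03 to 0.02). It gave 0.51 over the 2927 called genes (simulated −0.06 to 0.05) and 0.58 over the same 1300 genes (simulated −0.05 to 0.05). Neither all-gene value reached the bound of 0.5, which was set after the values were seen, so missing it settles nothing. Both leave the question open. A single proportional factor is argued against by the slopes of p53 targets and pericentral genes, which differed by 0.34 and by at least 0.27 without each library in turn. Cohorts were read from close animal numbers, which the titles do not define as such. Knockout minus wild-type differences that share no library, 1 of them between close numbers, correlated at r = 0.70. This cannot exclude a part for cohorts, because livers of 1 genotype also differed along the same change. With 2 DEN knockout livers, genotype and degree of injury stay open side by side.

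Of 41 interferon-stimulated genes 29 were higher in DEN knockout than in DEN wild-type liver (camera adjusted p = 5.3e-14, and adjusted p = 0.47 with an estimated correlation). A lower share of hepatocytes as the only change would raise other cell types alike, but the mean change of lymphocyte markers exceeded that of endothelial markers by 1.57 log2 units (permutation p = 1e-05, the smallest that 100000 resamples can give, as a description across genes). Endothelial markers themselves had a median of −0.06 in this comparison. The test cannot exclude a lower share beside other changes, since it takes a lower share as the only change. More leukocytes in DEN knockout than in DEN wild-type livers stay open as an explanation. The mean change of interferon-stimulated genes differed from that of pan-leukocyte genes by −0.08 (permutation p = 0.61), which does not show that both are equal. Medians were 1.49 for lymphocyte and 0.60 for monocyte and neutrophil markers, whose difference was not tested. Against PBS, lymphocyte markers had a median of −1.37 under DEN in wild type and of 0.12 in knockout. Interferon-stimulated genes had −1.08 and 0.17, so both lists differed more by a fall in wild type than by a rise in knockout. A degree of injury that varies among knockout livers stays open too, with a median difference of 0.35 between DENKO_141 and DENKO_309.

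For 872 genes the DEN response differed between the genotypes by the test of the interaction, and the named ones and the lists called by camera follow as log2 differences, the change in knockout minus that in wild type. Of the 38 named genes with a positive difference, 29 had negative changes in both genotypes that were smaller in size in knockout, 6 a negative change in wild type and a positive one in knockout, and 3, Lgals3, Cbr1 and Nfe2l2, positive changes that were larger in knockout. In order of size, the positive differences were those of Cyp1a2 (5.78), Hsd3b5 (5.13), Slco1a1 (4.91), Fam55b (4.65), Cyp2c55 (4.64), Serpina6 (4.33), Slc22a28 (4.18), Syt1 (3.96), Rgn (3.92), Akr1c6 (3.84), Cd8a (3.25), Itgax (3.07), Aurkb (2.90), Nkg7 (2.89), Tk1 (2.70), Otc (2.69), Ugt2b1 (2.69), Cxcl9 (2.68), Gulo (2.54), Cyp27a1 (2.27) and Cyp2c44 (2.26). Below these came Lgals3 (1.99), Mlxipl (1.93), Acss2 (1.93), Irf7 (1.71), Tm7sf2 (1.70), Alas2 (1.68), Il18 (1.55), Cbr1 (1.41), Psmb8 (1.26), Aox1 (1.21), Col3a1 (1.19), Shmt2 (1.12), Aqp11 (1.05), Mpeg1 (1.02), Reln (0.99), Slco2b1 (0.98) and Nfe2l2 (0.82).

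Of the 25 named genes with a negative difference, 20 had positive changes in both genotypes that were smaller in knockout and 5 a positive change in wild type and a negative one in knockout. The negative differences were those of Hist1h4c (−5.29), Igdcc4 (−5.07), Orm3 (−4.67), Bmper (−4.59), Gzmm (−3.22), Lcn2 (−3.16), Dclk2 (−2.70), Cidec (−2.60), Acot2 (−2.23), Cd14 (−2.17), Inhbb (−2.10), Fabp4 (−1.97), Plin2 (−1.91), Mcm7 (−1.84), Tnfrsf12a (−1.79), Lrrc51 (−1.61), Ppp1r15a (−1.53), Hsd17b13 (−1.47), Ddit3 (−1.34), Tfrc (−1.18), Btg1 (−1.18), Ehhadh (−1.03), Sdsl (−0.98), Zmat3 (−0.84) and Atg12 (−0.70). Of the 63 named genes, 53 lost the call without DENKO_141. Lists called with a positive difference had medians of 1.69 (T, NK and B lymphocytes), 1.41 (pericentral genes), 1.21 (cytochrome P450 enzymes), 1.20 (interferon-stimulated genes), 1.12 (cholesterol synthesis), 0.98 (male-biased genes), 0.81 (bile acid genes), 0.69 (fatty acid synthesis), 0.59 (Kupffer cells and macrophages), 0.45 (NRF2 targets), 0.36 (secreted proteins and amino acid metabolism) and 0.34 (other antioxidant enzymes). Lists called with a negative difference had medians of −1.13 (immediate early genes), −0.55 (PPAR-alpha targets), −0.44 (histones), −0.37 (endothelium), −0.32 (p53 targets) and −0.16 (acute phase). None of the 18 lists passed with an estimated correlation, and fry called only the pericentral (0.021) and lymphocyte (0.038) lists. The call was lost for fatty acid synthesis without DENKO_141 (0.063), for macrophages without DENWT_996 (0.07) or PBSWT_542 (0.093) and for other antioxidant enzymes without DENKO_309 (0.087) or DENWT_996 (0.053). It was lost for endothelium without DENWT_995 (0.18), PBSKO_544 (0.16) or PBSWT_541 (0.57) and for the acute phase without DENKO_141 (0.27), DENWT_307 (0.19) or PBSKO_549 (0.061). For histones it was lost in 7 of 11 fits, with DENKO_309 (0.089), DENWT_307 (0.12), DENWT_996 (0.057), PBSKO_154 (0.061), PBSKO_549 (0.1), PBSWT_541 (0.19) or PBSWT_545 (0.05) left out.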

How the results depend on the processing

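Alternatives were chosen before the data were examined. Of 9667 recomputed values for named genes, 9039 kept their direction and side of the threshold, 607 lost the call, 21 gained one and 0 reversed, where a change of sign of a value without a call counts as kept. For lists, of 2175 values 1974 kept both, 159 lost the call, 40 gained one and 2 reversed. With an absolute log2 fold change of at least 1, 3576 genes were called for DEN in wild type, 1463 for DEN in knockout and 1157 for knockout against wild type under DEN, by construction. DESeq2 called 1414 genes for the interaction. With the library labelled heterozygote counted as wild type, the interaction had 560 genes and knockout against wild type under PBS had 0, with Trim21 at −4.72 (adjusted p = 1), since a wild-type group that holds this library has a wide spread of Trim21. With an estimated correlation, camera called 0 lists for DEN in wild type, 1 for DEN in knockout, and 0 for each of knockout against wild type under PBS, under DEN, and the interaction, and fry called 0 under PBS and 2 for the interaction. NRF2 targets, knockout against wild type under DEN, had an adjusted p = 0.47 with an estimated correlation. The slope of the knockout on the wild-type response was 0.780 over genes called in knockout. Without each library in turn, the gene counts ranged from 1161 to 3168 for DEN in knockout, from 256 to 3356 for knockout against wild type under DEN and from 26 to 1161 for the interaction, and the lists called under PBS from 6 to 14. The camera adjusted p ranged from 0.0074 to 0.85 for cell cycle genes under DEN, from 1.9e-06 to 0.95 for interferon-stimulated genes under PBS, which were not called (0.68) but passed in the opposite direction without PBSKO_154 (0.03), and from 7.6e-11 to 0.97 for Kupffer cells and macrophages under PBS, called higher (0.0013) but on the other side of 0 and not passing without PBSWT_541 (0.97). Where construction does not show it, the cause was not tested. The fit on only the groups of a comparison gives no value for the interaction. Depth limits Ccnb1 and Il6, which had too few counts to test, and genes with about 1 CPM or less in every library, such as Cd8a and Tnf.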

Other observations

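The tests of other splits were chosen before their results were seen. Among further lists compared between DEN and PBS in wild-type liver, camera called those of histones, bile acid genes and secreted proteins, and not those of acute phase genes and cytokines. Histone genes rose in 13 of 17 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.018, 0.055 without DENWT_307, 0.065 without PBSWT_541, and adjusted p = 0.38 with an estimated correlation), with Hist1h2ac at 3.98 ± 0.40 (edgeR adjusted p = 4.1e-06), although members of this family may share reads. Bile acid genes fell in 15 of 22 and rose in 2, the same adjusted over the list alone (camera adjusted p = 4.1e-05, and adjusted p = 0.38 with an estimated correlation), with the sterol hydroxylase gene Cyp27a1 at −2.99 ± 0.26 (1.5e-06). Secreted proteins and enzymes of amino acid metabolism fell in 26 of 39 and rose in 1 (27 and 1 adjusted over the list alone, camera adjusted p = 1.9e-07, and adjusted p = 0.27 with an estimated correlation). Acute phase genes rose in 9 of 28 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.23), with lipocalin 2, Lcn2, at 5.15 ± 0.53 (4.1e-05). Cytokines, chemokines and adhesion genes rose in 12 of 27 and fell in 4, the same adjusted over the list alone (0.11, and 0.03 without DENWT_996), with Lif at 6.32 ± 0.29 (7.6e-09). With 1 of the 10 splits of the 6 libraries giving as many genes as the real one, which gave 7218 on these libraries alone against 0 in the highest other, the splits are too few for a share under 0.05.

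Of the following lists, camera called none between the DEN genotypes among those with enough members to be tested. Unfolded protein and ATF4 response genes were higher in knockout in 7 of 28 and lower in 5 (8 and 6 adjusted over the list alone, camera adjusted p = 0.92), with the stress regulators Ppp1r15a at −1.37 ± 0.24 (edgeR adjusted p = 0.0034, and 0.069 without DENKO_141) and Ddit3 at −1.13 ± 0.22 (0.0048, and 0.092 without DENKO_141). Genes of p62, KEAP1 and autophagy were higher in 3 of 23 and lower in 1 (1 and 1 adjusted over the list alone, camera adjusted p = 0.88). Periportal genes were higher in 2 of 25 and lower in 3, the same adjusted over the list alone (0.36, and called lower at 0.00077 without DENKO_141), with Hsd17b13, a lipid droplet dehydrogenase, at −1.79 ± 0.19 (0.00023). Stellate cell and matrix genes were higher in 4 of 30 and lower in 1, the same adjusted over the list alone (0.21), and cholangiocyte and progenitor genes in 1 and 1 of 18, the same adjusted over the list alone (0.2), with Tnfrsf12a at −1.52 ± 0.22 (0.0014). Heat shock genes were higher in 1 of 15 and lower in 0, the same adjusted over the list alone (0.15), and none of 19 circadian genes was called (0.89), also over the list alone. Of 3 erythroid genes 1 was higher and 1 lower, and of 4 adipose and pancreas genes 1 was higher and 1 lower. Among neighbours of Trim21, 19 of 83 (22.9%) were called under DEN against 22.1% of other genes.

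Under PBS, 3 of the 10 splits of the 6 libraries called as many genes as the real split, which called 1, and the highest other called 3, and the splits are too few for a share under 0.05.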
